A study of Mus musculus with 20 samples.

How the data were processed

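Gene expression was measured with a mouse Affymetrix array in MHC class II high medullary thymic epithelial cells, sorted by flow cytometry from individual thymi of Aire wild-type and knockout male mice. Per the labels' protocols, total RNA was isolated with Trizol and amplified in a pair of rounds as antisense RNA before biotin labelling, steps that can favour the 3' ends of transcripts. The deposited table holds 1 intensity per probe set and array on a linear scale, and per the submitters' processing notes these intensities were made with RMA, whose version and settings are not given in the sources used here. RMA usually corrects background and quantile-normalizes arrays together, which evens out array-wide shifts, but which arrays were normalized together is not stated. The scale was read from the values, which run from 6.55 to 18395 with medians near 90 on every array. No detection calls or background values were used here, so no probe set can be called undetected, and folds of probe sets near the bottom of the scale are understated if background remains.

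Groups were taken from the sample titles: B6 wild-type and knockout (3 and 3 mice), BALB (4 and 4) and NOD (3 and 3). Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested after taking log2. The annotation table used gave exactly 1 gene symbol for 34945 of these, several for 932 and did not list 9160, which are unnamed here. No symbol changed on matching gene identifiers to RefSeq (assembly GRCm38.p6, used for names and for the order of genes only). Each of 18193 genes was represented by its probe set with the highest mean over all arrays. Of the 131 genes named for the averaged effect, 53 had another probe set. Of 94 other probe sets 82 belonged to genes whose probe set used passed, and 51 of these 82 passed too, 1 with the opposite sign. The other 31 did not pass, and 14 of them had the opposite sign, so the values of a gene can depend on the probe set.

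The 6 group means were fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 14 residual degrees of freedom), with contrasts for knockout minus wild-type in each strain and averaged over strains, for strain differences among wild-type mice, and an F test over the strain differences of the knockout effect. Benjamini-Hochberg adjustment was made over all probe sets with a threshold of 0.05. Over all probe sets the averaged contrast had a median of 0.06, so calls of small size depend on the scaling. Gene lists, 32 in all with 390 of 428 entries measured, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists. Several lists share members, among them Mucl2, Csn1s2a, Fabp2, Tff3, Ins2, Apob, Ttr and Cd80. List members with no probe set of a single symbol, among them Mup1, Muc6 and Ins1, were not analysed here. The spread between mice was the SD of log2 values per probe set, its median over an Aire-dependent set was divided by the median over sets drawn 10000 times from the same 20 level bins, and the set of each strain was chosen by the contrasts of both other strains, 2-fold or more lower, in the fit of all 20 arrays.

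The rule for the genes named, the lists and most alternatives were fixed before the data were examined. The genes named are Aire, the 12 largest falls and 8 largest rises of the averaged effect with the same sign in 3 strains, the 5 largest falls and 3 largest rises in each strain without overlap between genotypes, the 8 widest strain ranges past the interaction test, the 4 largest wild-type strain differences each way without overlap, the 6 largest spreads, up to 4 members per list, and label checks. List members outside these, such as Rbp3, Svs2, Csn2 and Itga6, were named after their values were seen, to complete a list's count.

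Same-numbered mice of a strain were checked for shared deviations from their group means. All 4 BALB pairs and all 3 NOD pairs correlated above 0.1, and the numbers were taken as pairs there. In B6 1 of 3 pairs did not (r = -0.13), and the numbers were not taken as pairs. Sample codes in the labels fall into 4 runs, and 1 B6 mouse has none. In BALB, wild-type and knockout mice of different numbers in the same run also correlated above 0.1 (0.11 to 0.26). Same-numbered BALB pairs correlated more (0.46 to 0.66), and in NOD such mice of different numbers read 0.02 and 0.03. The limit of 0.1 alone therefore cannot tell a pair from a shared run. Alternatives covered scaling, a filter on dim probe sets, variance models, array weights, blocks, the arrays fitted, fold limits and leaving out each mouse. Those added later were a covariate for the Gapdh 3'/5' ratio, a covariate for dendritic cell and macrophage markers, merging 2 alike B6 knockout arrays, leaving out 3 B6 arrays, and the code run as a block for the lists.

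The code was tested on simulated data with 200 of 45037 probe sets changed. All simulated values were independent between probe sets and between arrays. They held no correlation between genes, no pairs and no code runs, so false calls in the real data can be more frequent. In the averaged contrast 63.2%, 95.5% and 100% of log2 changes of 0.5, 1 and 2 were recovered, and in the B6 contrast 22.1%, 71.2% and 98.5%. For BALB the shares were 29.4%, 77.3% and 98.5%, for NOD 20.6%, 63.6% and 97.0%, and for the interaction 7.35%, 59.1% and 92.4%. For wild-type BALB against B6 they were 26.5%, 77.3% and 97.0%, for NOD against B6 16.2%, 72.7% and 97.0%, and for NOD against BALB 22.1%, 77.3% and 97.0%. False calls made up 7.97% of calls in B6 and 5.67% or less in the other comparisons. The list test called 0 of 50 unshifted lists and found the shifted 1, and a spread ratio of 1.5 was recovered as 1.51. Python 3 with pandas and matplotlib prepared the tables and figures.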

Results

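The series measured gene expression with Affymetrix arrays in medullary thymic epithelial cells sorted from the thymi of individual male mice aged 3 to 4.5 weeks. These cells, gated as epithelial, negative for the haematopoietic marker CD45, intermediate for Ly51 and high for MHC class II, are the thymic cells that normally express Aire, a transcriptional regulator known for switching on genes of peripheral organs in the thymus. Aire wild-type (WT) and Aire knockout (KO) mice of 3 inbred backgrounds were compared: 3 WT and 3 KO mice in B6, 4 and 4 in BALB, and 3 and 3 in NOD, 20 arrays in all. The title of the series points to 2 questions, namely what Aire does in each genetic background and how individual mice of 1 background differ. The array medians lay between 86.3 and 90.9 intensity units and the highest probe set of each array between 16782 and 18395 units, so signal ranges were close to equal. The labels give 1 thymus per array, and the limma p-values below rest on the spread between mice within groups, pooled over all 20 arrays. That spread also holds differences between pairs of mice and between runs of sample codes. The number of mice, 3 or 4 per group, limits the precision.

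The Aire probe set was present in every mouse and was higher, not lower, in the mice labelled KO. Its log2 intensity was 10.73 ± 0.08 (SD, n = 3) in WT and 11.53 ± 0.04 (n = 3) in KO mice of B6, 10.25 ± 0.64 and 10.95 ± 0.29 in BALB (n = 4 and 4), and 11.19 ± 0.24 and 11.91 ± 0.12 in NOD (n = 3 and 3). Averaged over the strains the difference was 0.74 ± 0.14 (SE; limma, Benjamini-Hochberg adjusted p = 0.00104), and 9 of the 10 KO mice lay above all WT mice of their strain. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so it checks nothing about the genotype, and KO below means labelled KO. The Y-linked Eif2s3y read 10.71 ± 0.35, 10.11 ± 0.03 and 10.46 ± 0.07 in WT mice of B6, BALB and NOD, with no female mice for comparison. The strain labels were checked on genes that differ between the strains. H2-Ea, an MHC class II gene whose promoter is deleted in the B6 and NOD haplotypes, read 11.87 ± 0.27 in BALB WT mice and 9.23 ± 0.27 and 9.29 ± 0.11 in B6 and NOD. Nnt, partly deleted in some B6 substrains, read 8.58 ± 0.37 in B6 and 9.32 ± 0.22 and 9.79 ± 0.17 in BALB and NOD, and Ddx3y was not analysed here.

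Among genes whose effect had the same sign in all 3 strains, the largest fall in KO mice was that of Hbb-y, an embryonic globin of a family with similar sequences, whose log2 difference averaged over the strains was -6.52 ± 0.20 (SE), a 91.9-fold fall (limma, Benjamini-Hochberg adjusted p = 1.86e-13). It was followed by Crh, the hypothalamic hormone that drives the stress axis (-5.64 ± 0.19), Mucl2, a salivary secretory protein listed in older work as Spt1 (-5.38 ± 0.24), the melatonin-related receptor Gpr50 (-5.09 ± 0.14), the gut and brain peptide neurotensin, Nts (-4.94 ± 0.13), and the milk casein Csn1s2a (-4.63 ± 0.19). Fgg, a fibrinogen chain made by the liver (-3.99 ± 0.14), BC080696 (-3.98 ± 0.15), the secreted protein C1qtnf3 (-3.91 ± 0.17), Cilp of cartilage (-3.88 ± 0.13), Asb4 (-3.87 ± 0.16) and the gut antimicrobial lectin Reg3b (-3.87 ± 0.22) completed the 12 largest falls. For each of these 12 genes all 10 KO mice lay below all WT mice of their strain. Other, dimmer probe sets of these genes, where the array has any, read -6.66 and -1.74 for Hbb-y, -0.43 for Gpr50, -4.28, 0.14, -0.27 and -0.12 for Csn1s2a, -2.66 for Asb4 and -2.31 for Reg3b.

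**Figure D1:**
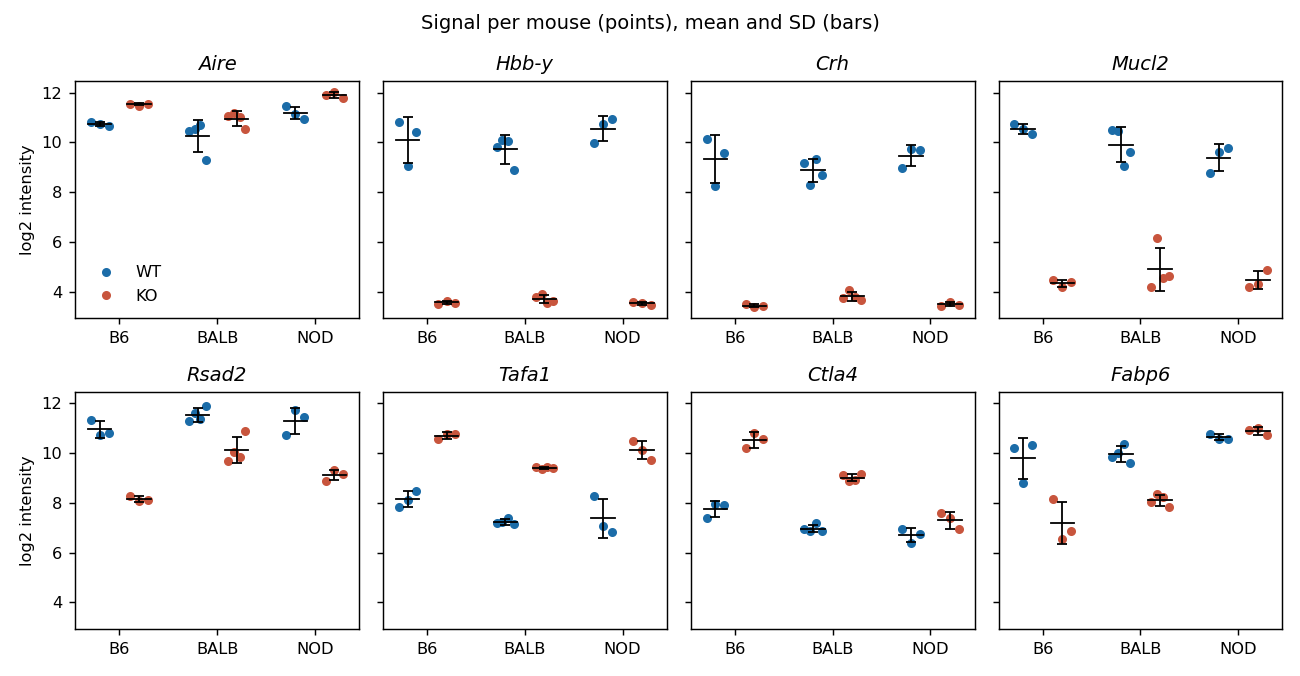
Log2 intensity (vertical axis) of 8 genes in each mouse of the 3 strains (horizontal axis). Points are mice, horizontal lines are group means and bars are SDs; Hbb-y, Crh and Mucl2 fell in the KO mice of every strain, Aire and Tafa1 read higher in them, and the KO effect on Ctla4 and Fabp6 differed between strains.

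A smaller group of genes rose in KO mice. Tafa1, a secreted neuronal protein, rose by 2.48 ± 0.15 (SE) on the log2 scale, a 5.6-fold rise (limma, adjusted p = 8.85e-10), and all 10 KO mice lay above all WT mice of their strain. Spock3, a matrix proteoglycan (1.97 ± 0.26), 1810006J02Rik (1.95 ± 0.17), the T cell inhibitory receptor Ctla4 (1.81 ± 0.11), the cartilage proteoglycan Epyc (1.80 ± 0.26), the DNA methyltransferase cofactor Dnmt3l (1.79 ± 0.17), Tmem241 (1.75 ± 0.11) and Ptchd4 (1.74 ± 0.17) were the next largest rises. Other probe sets of these genes read 0.12 for Spock3 and 0.11 and 0.13 for Tmem241, none of which passed, and 0.99 for Ptchd4. The effect on Ctla4 differed between strains (adjusted p of the strain difference = 0.00292), and for Ctla4 and Ptchd4 9 of 10 KO mice lay above all WT mice of their strain.

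Over all 45037 probe sets tested, 9277 passed an adjusted p of 0.05 in the averaged contrast (limma), 4537 lower and 4740 higher in KO mice. Among the 1163 of these that changed at least 2-fold, 965 were lower and 198 higher, so 83.0% of the larger changes were falls, and 62 probe sets fell at least 8-fold while 0 rose as much (limma, out of 15347 probe sets at an unadjusted p under 0.05). The 965 falling probe sets had a median WT log2 intensity of 7.70, against 6.498 for all probe sets. Hbb-y read 3.57 ± 0.07 in B6 KO mice, below the log2 value of 3.77 that marks the lowest 5% of all values, so its fold is understated if background remains in these values. With the mice paired by strain and replicate number the averaged contrast called 16664 probe sets, which held 9272 of the 9277. That fit also paired the B6 mice, whose numbers were not taken as pairs.

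Falls were frequent in the gene lists of several organs. Of 18 measured pancreas genes 17 fell, among them the islet hormones Ppy (-2.86) and Iapp (-2.81), the exocrine Reg1 (-2.27) and the trypsin inhibitor Spink1 (-2.25), with a list median of -1.02 on the log2 scale (camera, adjusted p = 3.00e-13). In the intestine list 15 of 17 fell, led by Reg3b, the fatty acid binding protein Fabp2 (-2.80), the goblet cell lectin Zg16 (-2.66) and the trefoil peptide Tff3 (-2.53; adjusted p = 1.27e-13). Of 18 liver genes 13 fell, with the fibrinogen chains Fgg and Fgb (-3.28), Itih3 (-3.10) and haptoglobin, Hp (-2.11), at the top (adjusted p = 1.57e-10). The salivary and lacrimal list lost 10 of 12 genes, including Mucl1 (-3.05), the kallikrein Klk1b5 (-2.80), whose close paralogs can share probes, and Bpifa2 (-2.06; adjusted p = 1.64e-09). In the stomach list 8 of 11 fell, led by the gastrokines Gkn2 (-1.98) and Gkn1 (-1.63; adjusted p = 6.49e-07). A list of antigens described as Aire-dependent in earlier work had 8 of 10 measured members lower, from Mucl2 and Csn1s2a to insulin, Ins2 (-1.15), while the retinal Rbp3 was slightly higher (0.17) and Svs2 did not pass (0.03; adjusted p for the list = 9.09e-09). These 6 lists also passed with an estimated correlation between genes, at adjusted p from 0.00301 to 0.00654, and the counts did not change when adjusted over the list alone except that 14 liver genes then fell. Several members, such as Mucl2, Csn1s2a and Fabp2, stand in 2 of the lists.

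**Figure D2:**
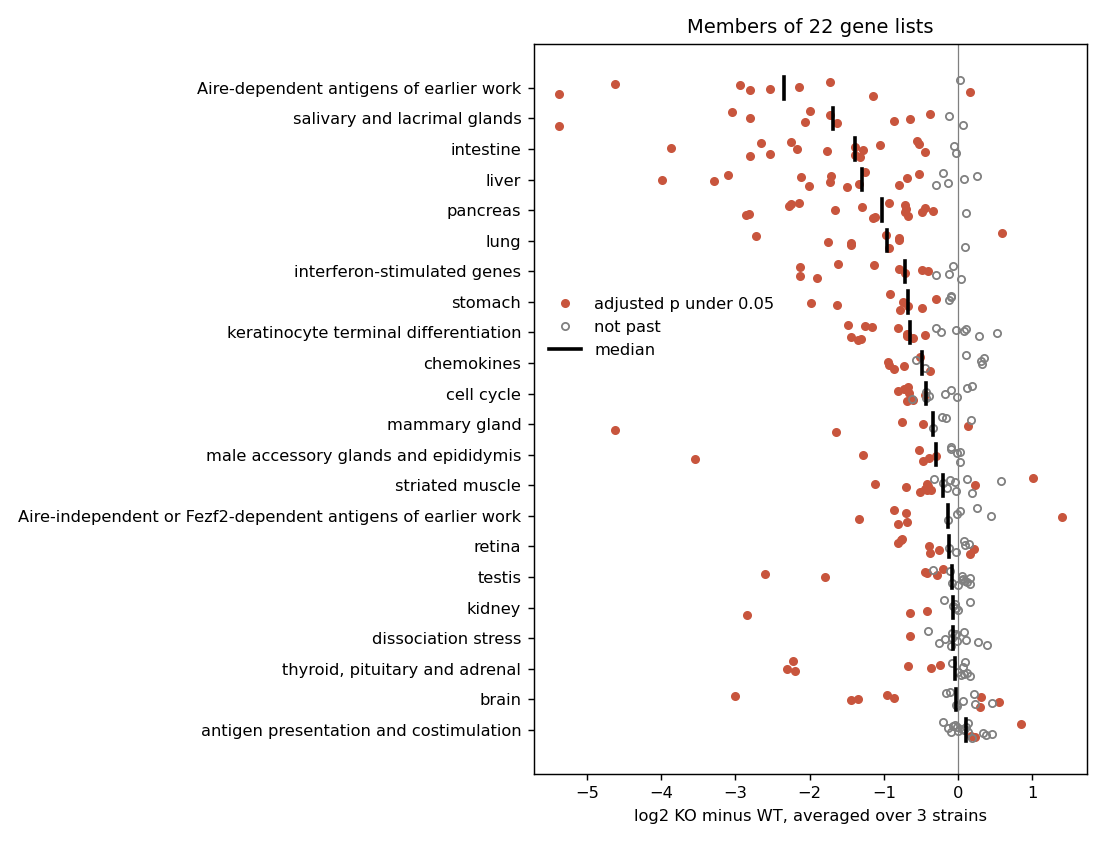
Log2 difference between KO and WT mice averaged over the 3 strains (horizontal axis) for each measured member of 22 gene lists (rows). Filled points passed adjusted p 0.05 (limma), open points did not, and black bars are list medians, which ran from -2.34 for the antigens of earlier work to 0.10 for antigen presentation.

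Other organ lists fell in part. Of 10 lung genes 8 fell, among them Bpifa1 (-2.73), the club cell protein Scgb1a1 (-1.76) and the surfactant proteins Sftpc (-1.44; other probe set 0.07) and Sftpd (-1.44), and Ager rose (0.60; camera, adjusted p = 3.92e-05, and adjusted p = 0.0515 with an estimated correlation). In the male accessory gland list 6 of 11 fell, with the seminal vesicle protein Svs4 (-3.54) far ahead of Pate4 (-1.29; adjusted p = 0.00182, and adjusted p = 0.0564 with an estimated correlation). The mammary list rested on Csn1s2a and Csn1s1 (-1.64), with 4 of 9 lower and the casein Csn2 slightly higher (0.13; adjusted p = 0.0267, and adjusted p = 0.18 with an estimated correlation). Of 18 genes of the cornifying keratinocyte 11 fell, led by Lce3a (-1.49), loricrin, Lor (-1.44; other probe sets -1.19 and 0.08), Krt1 (-1.34) and Krt10 (-1.30), at an adjusted p of 0.000369, and an adjusted p of 0.241 with an estimated correlation. Adjusted over the list alone, 8 lung, 6 male accessory, 5 mammary and 11 keratinocyte genes fell, and 1 lung, 2 mammary and 1 keratinocyte gene rose.

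Lists of retina, brain, striated muscle, testis, kidney and the endocrine glands did not pass as lists (camera, adjusted p from 0.0542 to 0.372), although single members fell strongly. All 6 passed as lower with fry (adjusted p from 3.38e-08 to 7.23e-05). The neuropeptide precursor Tac1 changed by -3.005 and the neurofilament Nefl by -1.45 in the brain list, where 5 of 16 genes fell and 3 rose, but another probe set of Tac1 read 0.18 (adjusted p = 0.113), and another of Nefl -2.76. The germ cell helicase Ddx4 (-2.60) and the sperm lactate dehydrogenase Ldhc (-1.79) were among 6 of 17 testis genes that fell. The kidney's uromodulin, Umod (-2.84), was among 3 of 9 kidney genes that fell, and the hormones Cga (-2.31), Pth (-2.22) and Pomc (-2.19) were among 6 of 14 in the endocrine list. In the retina list 6 of 13 fell, led by Rcvrn (-0.81), and 2 rose. In striated muscle 8 of 19 fell, led by the acetylcholine receptor subunit Chrna1 (-1.11), and 2 rose, phospholamban, Pln, by 1.01. Among antigens that earlier work had placed outside Aire control, 5 of 11 fell, including Apob (-1.33; other probe set 0.11) and Gad1 (-0.86; other probe set 0.05), Maoa rose (1.41) and 5 did not pass (list adjusted p = 0.372). Adjusted over the list alone, the numbers of falls were 6 in retina, 5 in brain, 9 in striated muscle, 7 in testis, 4 in kidney, 6 in the endocrine list and 5 in this last list. The numbers of rises were 3 in retina, 4 in brain, 3 in striated muscle, 1 in kidney and 2 in this last list.

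Genes induced by interferon also fell. Of 13 measured members 9 were lower in KO mice and 0 higher (limma; 9 also adjusted over the list alone), among them Rsad2, which encodes the antiviral enzyme viperin (-2.13 ± 0.15), Ifit3 (-2.13 ± 0.22), Ifit2 (-1.90 ± 0.18) and the guanylate binding protein Gbp3 (-1.61 ± 0.16). The list shift had an adjusted p of 2.50e-06 with camera, and an adjusted p of 0.0564 with an estimated correlation. Among 12 chemokines 6 fell (7 fell and 2 rose adjusted over the list alone), among them Cxcl9 (-0.95), Ccl22 (-0.93), Ccl5 (-0.86) and Ccl20 (-0.73), and the list did not pass (adjusted p = 0.0884). Cell cycle genes were lower in 7 of 16 (10 lower and 1 higher adjusted over the list alone), with Cdc20 at -0.81, Mcm5 at -0.73, Mki67 at -0.68 and Rrm2 at -0.68. Other probe sets read -0.64 and -0.29 for Cdc20, -0.29 and 0.23 for Mcm5, and -0.42 and -0.48 for Rrm2. Of these only the -0.64 of Cdc20 passed. The cell cycle list passed at an adjusted p of 0.0226, and had an adjusted p of 0.54 with an estimated correlation.

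Most genes of antigen presentation and costimulation did not pass. Of 19 measured genes 16 did not pass, 3 rose and 0 fell (limma): the costimulator Cd80 by 0.85 and the MHC class II chains H2-Ab1 by 0.22 and H2-Eb1 by 0.18 (list adjusted p = 0.0884; 2 rose adjusted over the list alone). Markers of mature medullary epithelium behaved alike, with 11 of 14 not past the threshold, Cd80, Aire and Relb (0.63) higher and 0 lower (adjusted p = 0.0884; 3 rose adjusted over the list alone). Among 7 markers of immature medullary epithelium 4 fell, led by Krt15 (-1.01) and Krt5 (-0.69), and 1 rose, Itga6 by 0.29 (adjusted p = 0.259; 4 fell and 1 rose adjusted over the list alone). Of 14 dissociation stress genes 1 fell, Ier3 (-0.64; adjusted p = 0.757; 1 adjusted over the list alone).

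Markers of other cell types did not pass as lists with camera (adjusted p from 0.22 for thymocytes to 0.959 for red blood cells). The B cell list passed as higher with fry (adjusted p = 0.0358), which asks only whether members move one way on balance. In the fibroblast list 4 of 8 genes fell, the collagens Col3a1 (-1.12), Col1a2 (-0.81) and Col1a1 (-0.77) among them. Another 3 rose, decorin, Dcn, by 1.53. Other probe sets read -0.14 for Col3a1, -0.77 and 0.11 for Col1a2, -0.08 for Col1a1 and 0.31 for Dcn. Of the cortical epithelial markers, 1 of 9 fell, Ctsl (-0.78), and 2 rose, Tbata (0.61) and Ly75 (0.52). Another probe set of Ctsl read 0.17 and did not pass. Cd34, in the endothelial list, fell by 2.11 as 1 of 8 and Pecam1 rose by 0.21. The B cell list held 2 rises in 7 genes, Cr2 (1.44) and Blk (0.25), and the dendritic cell and macrophage list 1 fall, Adgre1 (-1.38), and 1 rise, Fcer1g (0.53), in 11. Of 11 thymocyte genes Cd3g (-0.92) and Dntt (-0.67) fell, of 5 tuft cell genes Dclk1 fell (-0.60), and of 3 red blood cell genes Slc4a1 fell (-0.38), while its other probe sets read 0.15 and -1.57. Other probe sets of Dntt read -0.10 and -0.36 and did not pass, and those of Dclk1 ran from -1.53 to 0.04. Adjusted over the list alone, the falls and rises were 4 and 3 in fibroblasts, 2 and 2 in cortical epithelium, 1 and 2 in endothelium, 2 and 2 in B cells, 1 and 1 in dendritic cells and macrophages, 2 and 0 in thymocytes, 1 and 0 in tuft cells and 1 and 1 in red blood cells. The median was above 0 and the mean below 0 for cortical epithelium (0.05 and -0.01), B cells (0.07 and -0.01), endothelium (0.07 and -0.18) and red blood cells (0.07 and -0.04). The sort gated on cells negative for CD45. Even so, the mean log2 of the dendritic cell and macrophage markers ran from 8.07 to 10.06 over the arrays. The median of all probe sets in WT mice was 6.498, so haematopoietic cells cannot be called absent.

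The submitters' sample codes fall into 4 runs of close numbers, whose meaning is not given. All 12 lists that passed had a negative median in each of the 5 sets of same-strain WT and KO mice within a run. The medians ran from -3.20 to -1.56 for the antigens of earlier work and from -0.77 to -0.45 for the interferon list, and all 12 passed with the run as a block. The lists passed on these same mice, so the signs within runs are no independent support.

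In B6 mice the largest falls in KO mice were those of Hbb-y (-6.53 ± 0.36, SE, on the log2 scale), Mucl2 (-6.19 ± 0.43), Nts (-6.08 ± 0.23), Crh (-5.89 ± 0.35) and Gpr50 (-5.79 ± 0.25). The largest rises were those of Ctla4 (2.79 ± 0.20), Tafa1 (2.55 ± 0.27) and 4833422C13Rik (2.42 ± 0.19). In all, 3880 probe sets passed (limma, adjusted p 0.05), 2495 lower and 1385 higher, of which 1343 and 409 changed at least 2-fold. WT mouse 2 and KO mice 2 and 3 stood apart from the other B6 arrays, with log2 Gapdh 3' minus 5' signals of 1.90, 1.68 and 1.84, below the 2.15 of the lowest array of the other strains. Without these 3 arrays, left out after seeing the data, 1245 probe sets passed, 1200 of them also called with all arrays, but that fit holds 1 B6 KO mouse against 2 WT mice and assumes that the lone mouse varies like the other groups. With KO mice 2 and 3, whose arrays were the most alike of all pairs, counted as 1 sample, 2524 passed, and without KO mouse 3 alone 2387 did.

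In BALB mice the same 5 genes led the falls, Hbb-y at -6.01 ± 0.31, Crh at -5.06 ± 0.30, Mucl2 at -5.01 ± 0.37, Gpr50 at -4.77 ± 0.22 and Nts at -4.51 ± 0.20 (log2, SE). Tafa1 (2.17 ± 0.23), B230209E15Rik (2.13 ± 0.17) and Ctla4 (2.04 ± 0.17) rose most. The test called 3079 probe sets (limma), 1920 lower and 1159 higher, with 828 and 165 at 2-fold or more. The replicate numbers were taken to pair the BALB mice, and with the pairs as a block 7787 probe sets passed, all 3079 among them. With the code run as a block 4911 passed, and the 1920 lower calls had medians of -0.97 and -0.84 within the 2 runs, the higher calls 0.61 and 0.62. The calls were made on these same mice, so the medians within runs are no independent support.

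In NOD mice Hbb-y changed by -7.03 ± 0.36, Crh by -5.98 ± 0.35, Mucl2 by -4.94 ± 0.43, Csn1s2a by -4.83 ± 0.35 and Gpr50 by -4.70 ± 0.25 (log2, SE). Tafa1 (2.73 ± 0.27), the serpin Serpina9 (2.62 ± 0.23) and Lrmda (2.30 ± 0.56) rose most. There were 1903 calls (limma), 1264 lower and 639 higher, with 746 and 208 at 2-fold or more. The replicate numbers were taken to pair the NOD mice too, and 5112 probe sets passed with the pairs as a block, all 1903 among them, and 3090 with the code run as a block. The lower calls had medians of -1.09 and -1.17 within the 2 runs, the first of which holds 1 mouse of each genotype. These medians come from the mice that made the calls and are no independent support. Fewer passed without WT mouse 2 (1180), WT mouse 3 (1209) or KO mouse 1 (1267).

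Many probe sets fell in more than 1 strain. B6 and BALB shared 1359 lower calls, where independent lists of these sizes would share 106, B6 and NOD shared 1038 (70.0 expected), BALB and NOD 891 (53.9 expected), and 828 were lower in all 3 strains. Shared in all 3 were also 241 higher calls, and 16 probe sets were called in opposite directions in a pair of strains. These comparisons use different mice in each strain. Across probe sets, which are not independent replicates, the log2 effects correlated at r = 0.80 between B6 and BALB, 0.78 between B6 and NOD and 0.76 between BALB and NOD.

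Among probe sets chosen on the averaged effect, changes in both directions were larger in B6 than in the other strains. The 965 probe sets that fell at least 2-fold on average had median log2 changes of -1.84 in B6, -1.36 in BALB and -1.38 in NOD, and Nts, for example, fell by 6.08, 4.51 and 4.23 (limma, adjusted p for the strain difference = 0.0197). In a test chosen after these medians were seen, the change of the set was weaker in BALB than in B6 by a median of 0.52 (fry, adjusted p = 0.00304) and weaker in NOD than in B6 by 0.37 (adjusted p = 0.00839), while NOD and BALB differed by -0.05 (adjusted p = 0.563). B6 WT mouse 2 and KO mice 2 and 3, which stood apart, fall unequally on the genotypes. Without them the set was weaker than in B6 by 0.55 in BALB and 0.40 in NOD, with a lone B6 KO mouse left. The rises were not checked this way.

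For single genes the test of the strain difference in the KO effect passed in 196 of 45037 probe sets (limma, adjusted p 0.05), standing for 154 genes. The KO effect on 1700110I01Rik was -3.18 in NOD against -0.94 and -0.25 in B6 and BALB (adjusted p = 0.000456). For Gatm, the first enzyme of creatine synthesis, it was -3.88, -1.24 and -0.99 in B6, BALB and NOD, and for Khdc1a -3.01, -0.76 and -0.52. Khdc1a already read lower in WT mice of BALB and NOD than of B6 (values below), which leaves less room for a fall there. Some of these genes are known from the gut epithelium. The effect on the ileal bile acid binding protein Fabp6 was -2.60 and -1.84 in B6 and BALB and 0.25 in NOD, that on Fabp1 -1.66 and -2.46 in B6 and NOD and 0.16 in BALB, and that on Krt20 -0.70, 0.34 and -2.26 in B6, BALB and NOD. For Cst9 it was -2.37, 0.23 and -1.40, for 4833422C13Rik 2.42, 0.47 and -0.02, and for Ctla4 2.79, 2.04 and 0.61. The count was 1284 with the replicate block and 93 without the 3 B6 arrays that stood apart, where a lone B6 KO mouse is assumed to vary like the other groups. The replicate block also paired the B6 mice, whose numbers were not taken as pairs. Of 100 regroupings of the mice that part every BALB and NOD pair, the real one included, 7 called as many, and the other 6 all set the 3 B6 arrays that stood apart against the rest.

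**Figure D3:**
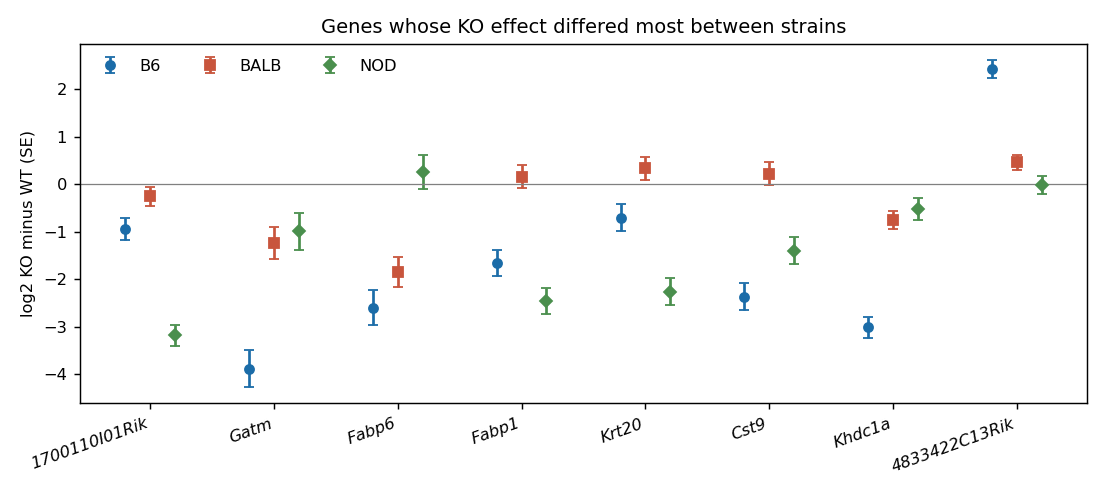
Log2 difference between KO and WT mice with its SE (vertical axis) in each strain for the 8 genes with the widest range of strain effects among those whose strain difference passed adjusted p 0.05 (limma). Fabp1, Krt20 and Cst9 read above 0 in BALB and below 0 in B6 and NOD.

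Among WT mice, BALB and B6 differed most at the MHC class I gene H2-Q2, with a log2 intensity of 9.88 ± 0.34 (SD, n = 3) in B6 and 3.38 ± 0.11 (n = 4) in BALB, where it lay in the lowest 5% of all values. Khdc1a (-3.80 ± 0.21, SE), Trim34a (-3.64 ± 0.35) and Trim12a (-3.52 ± 0.27), the last 2 from a Trim gene family with close paralogs, were also lower in BALB. The Paneth cell defensin Defa31, also of a family of near-identical copies (5.60 ± 0.34), Ccnb1ip1, a meiotic recombination gene (4.51 ± 0.33), the circadian factor Arntl2 (3.72 ± 0.20) and Rbm45 (3.68 ± 0.26) were higher in BALB. The test called 2747 probe sets (limma), 1589 lower and 1158 higher in BALB. Of the calls, 1723 were also called in the same direction between KO mice of these strains (170 expected from independent lists). The lists are not independent, since WT and KO mice share code runs and, in BALB, pairs. A run effect could therefore recur in KO mice, and 170 is no baseline for an effect of strain. No code run holds WT mice of both B6 and BALB, so strain and run cannot be told apart. With the code run as a random block 1179 passed, with the WT arrays alone 938, and without B6 WT mouse 2 or 3 1673 or 1744.

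NOD WT mice lacked most signal of Trim12c (4.22 ± 0.05 in NOD, 9.36 ± 0.38 in B6; SD, n = 3 and 3) and had a log2 difference from B6 of -5.03 ± 0.11 (SE) for D17H6S56E-5, -4.17 ± 0.23 for Khdc1a and -4.01 ± 0.22 for the prokineticin receptor Prokr2. The zinc finger gene Zfp979 (6.54 ± 0.19), Defa31 (4.66 ± 0.37), Ccnb1ip1 (4.26 ± 0.36) and E330020D12Rik (3.98 ± 0.53) were higher in NOD. In total 3172 probe sets passed (limma), 2031 lower and 1141 higher in NOD. Of these, 1897 were also called in the same direction between KO mice (166 expected from independent lists, which these are not). No code run holds WT mice of both B6 and NOD either, so strain and run cannot be told apart. With the code run as a random block 1717 passed, with the WT arrays alone 1355, without NOD WT mouse 2 1973, and without B6 WT mouse 2 2039.

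Between NOD and BALB WT mice the widest gaps were again Zfp979 (6.33 ± 0.18, SE), H2-Q2 (5.38 ± 0.17), the ribonuclease Ang3 (4.02 ± 0.30) and Trim5 (3.40 ± 0.21) on the higher side, and Trim12c (-5.31 ± 0.16), D17H6S56E-5 (-4.73 ± 0.10), Crym (-3.61 ± 0.19) and Prokr2 (-3.59 ± 0.20) on the lower side. The test called 2764 probe sets (limma), 1648 lower and 1116 higher in NOD. Of these, 1749 were also called in the same direction between KO mice (125 expected from independent lists, which these are not). The mean log2 of dendritic cell and macrophage markers was 8.32, 9.42 and 10.06 in the NOD WT mice and between 8.29 and 8.89 in the BALB WT mice. In the run that holds WT mice of both strains, 1 NOD and 2 BALB, the lower calls had a median of -0.89 and the higher calls 0.76. The calls were made in part on these mice, so their signs within the run are no independent support. With the code run as a random block 2769 passed, with the WT arrays alone 1613, and without NOD WT mouse 2 or 3 1792 or 1799. Of the probe sets that fell in KO mice a larger share was called between WT strains than of all probe sets, a difference that was not tested: 21.1% of the 965 against 6.10% of all probe sets for BALB and B6, 24.97% against 7.04% for NOD and B6, and 22.1% against 6.14% for NOD and BALB. In the same order, 204, 241 and 213 of the 965 were called between WT strains and 194, 174 and 177 between KO strains. Of all probe sets, 5483, 4514 and 3959 were called between KO strains, against 2747, 3172 and 2764 between WT strains. The 965 were chosen in part on the same WT mice and were not matched for level.

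Individual WT mice of 1 strain differed more in Aire-dependent probe sets than in others of the same level. For each strain the set held the probe sets past adjusted p 0.05 and at least 2-fold lower in the KO mice of both other strains. Its folds came from other mice, but the variance in the test was pooled over all 20 arrays, the mice measured included. The median SD between WT mice was 0.34 on the log2 scale in B6 (492 probe sets, n = 3), 0.38 in BALB (624, n = 4) and 0.29 in NOD (665, n = 3), against 0.24, 0.22 and 0.15 for level-matched probe sets. The ratios were 1.44, 1.69 and 1.91, with a mean of 1.68 ± 0.24 (SD over 3 strains), and each lay above all 10000 random matched sets. These sets were drawn over probe sets in the same mice, and probe sets are not independent. The rank therefore says nothing of how the ratio would vary with other mice. The members with the largest spread were Tcfl5, Gsdmc2, the growth factor Ereg, Tmsb15a, the metallothionein Mt4 and Ceacam11. In NOD the ratio was 1.48 without WT mouse 1 and 2.33 without WT mouse 3, and in BALB 1.44 without WT mouse 4. The same sets, matched on KO levels, gave ratios of 1.38, 1.44 and 1.58 in KO mice. These ratios are not independent of the WT ratios, since same-numbered WT and KO mice of BALB and NOD shared deviations.

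**Figure D4:**
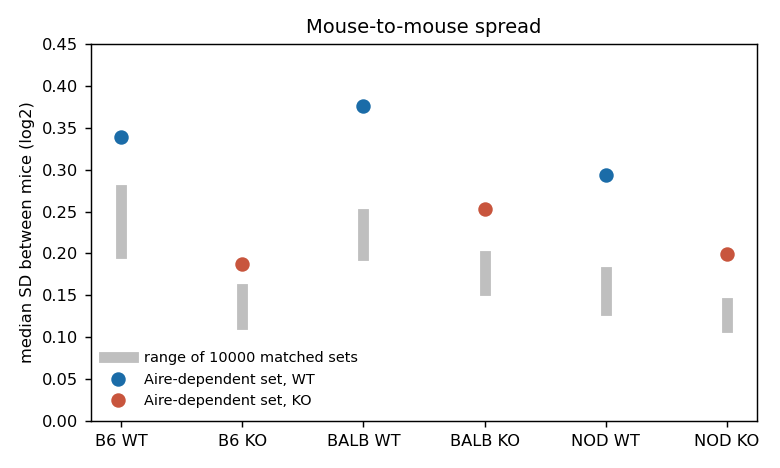
Median SD between mice of 1 group (vertical axis, log2) for the Aire-dependent probe sets of each strain and genotype (points) and the range over 10000 level-matched random sets (grey bars). Every point lies above its bar, with WT ratios of 1.44, 1.69 and 1.91.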

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

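The tests on code runs and haematopoietic markers, the 4 tests on the spread, the set test of the fall by strain, the splits of mice and the separation of the probe mismatch test into 3 comparisons and by direction were chosen only after the result was seen.

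BALB WT mouse 4 stood apart from the other 3 BALB WT mice in Aire itself, which read 9.31 against 10.48 to 10.71. In the same mouse H2-Eb1 read 13.07 (others 13.19 to 13.20), Mcm5 7.57 (8.55 to 8.75), Ppy 8.04 (8.54 to 8.60), Nefl 8.42 (9.44 to 9.61) and Pomc 7.87 (9.23 to 9.38), all lower, while Krt1 read 8.47 (7.29 to 7.33), Iapp 12.74 (11.98 to 12.06) and Ly75 9.44 (8.70 to 8.80), all higher. Its Aire-dependent probe sets deviated by a median of -0.26 from the WT mean of the strain. In B6 WT mouse 2 this value was -0.11, against -2.17 to -2.13 in B6 KO mice (a mislabelled mouse was considered there and not pursued after this value was seen). Among other BALB WT mice, mouse 2 had the lowest H2-Q2 (3.21) and Uty (6.89) and the highest Eif2s3y (10.16), and mouse 3 the lowest mean of dendritic cell and macrophage markers (8.29 against 8.81 to 8.89). BALB KO mouse 4, of the same number and run as WT mouse 4, also had the lowest Aire of its group (10.53 against 11.01 to 11.20).

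Among BALB KO mice, mouse 4 lay apart with Ccnb1ip1 at 10.52 (others 11.47 to 11.63), Lrmda at 8.13, Umod at 6.51 and Gsdmc2 at 3.52. KO mouse 2 lay apart with H2-Q2 at 3.92, E330020D12Rik at 6.88, Bpifa2 at 5.92, Guca1a at 4.71, Pth at 5.42 and Gbp3 at 9.87 (others 9.06 to 9.12). KO mouse 3 lay apart with Tcfl5 at 5.79, a cortical epithelial marker mean of 9.16 and a red blood cell marker mean of 5.81 (others 6.06 to 6.08), and KO mouse 1 with Eif2s3y at 9.99. Chance places about 1 in 20 groups beyond this limit, and 27 of 338 groups of 4 values tested did so (7.99%).

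The KO effect differed between strains for 14 named genes (limma, adjusted p of the interaction). The values were 0.000456 for 4833422C13Rik and for 1700110I01Rik, 0.00143 for Khdc1a, 0.00292 for Ctla4, 0.00451 for Fabp1, 0.0049 for Serpina9, 0.00753 for Krt20 and for Cst9, 0.0197 for Nts, 0.024 for Gatm, 0.0293 for Fabp6, 0.0336 for Fabp2, 0.0487 for B230209E15Rik and 0.0488 for Bpifa2. The fall of the set of 965 probe sets, chosen in part on the same mice, was weaker than in B6 by a median log2 of 0.52 in BALB and 0.37 in NOD.

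In B6, WT mouse 2 and KO mice 2 and 3 differed from the other 3 arrays alike in both genotypes, with r = 0.81 across probe sets between the WT and the KO difference and 1146 probe sets shifted at least 2-fold the same way in both. They had the lowest Gapdh 3'/5' signals of all arrays, and across probe sets their difference correlated at r = -0.25 with the slope on that signal in BALB and NOD (-0.28 to -0.21 leaving out an array), between the limits set beforehand, so an effect of RNA amplification stays open. WT mouse 3, of the same code run, deviated against KO mice 2 and 3 (mean r = -0.20), but a condition added later asks for more than 1 array, so the run stays open too. Markers of haematopoietic cells had a largest median shift of 0.12 with 14 of 29 members higher, and members that go both ways (SD 0.55, a condition added later) decide nothing, while no biological explanation was tested.

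Strain differences among WT mice may come in part from alleles that mismatch the probes: in genes with another probe set above the array median, the second probe set had the same sign in 88.1% of genes called between NOD and B6, 88.1% between NOD and BALB and 83.8% between BALB and B6 (95% intervals 82.7 to 92.3, 81.8 to 92.8 and 75.3 to 90.3), which argues against mismatches as the whole cause in the first 2. Mismatches to alleles other than B6 lower the signal of the other strain, but 42.2% of the calls were higher in BALB and 36.0% in NOD, and of genes lower than in B6 94.5% (84.9 to 98.9) in BALB and 89.7% (83.0 to 94.4) in NOD had the same sign, which argues against them as the whole cause for BALB too. Of genes higher than in B6 72.0% (57.5 to 83.8) in BALB and 85.1% (74.3 to 92.6) in NOD had the same sign, so some of these differences depend on the probe set, from a cause that was not tested. The second probe set showed a median of 0.55, 0.58 and 0.56 of the difference in the same order, against 0.73, 0.80 and 0.67 for the KO effect in B6, BALB and NOD, so a part from mismatches stays open. With the dendritic cell and macrophage marker mean as a covariate 83.4% of the calls between NOD and BALB were kept, which argues against such cells as the whole cause, and the strain itself stays open, untested, as the biological explanation.

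The larger spread of Aire-dependent probe sets between WT mice (mean ratio 1.68) lay above all level-matched random sets in each strain. For these mice this argues against array noise that depends on level alone. The random sets hold the same mice, so the uncertainty between mice was not measured. Removing a single shift per mouse left a lowest ratio of 1.39, and the lowest ratio within a code run was 1.19, so neither a common shift nor the runs account for all of it. A candidate explanation is that these genes vary whether or not Aire is present: in KO mice, at their own level, the mean ratio was 1.47. In BALB and NOD, however, same-numbered WT and KO mice shared deviations (r from 0.31 to 0.67), so the WT and KO ratios are not independent. What a pair shares was not removed and could raise both, so this comparison cannot tell it from a property of the genes. Which part of the WT excess needs Aire was not tested.

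Other groupings of the same mice were run for each count. In B6, where 3 against 3 mice make 10 splits, too few for a share under 0.05, 2 splits, the real one included, gave at least the real 3880 calls. The highest other, 6371, set the 3 arrays named above against the rest, which points to that structure of the samples. In NOD and for NOD against B6 the 10 splits are also too few, with 1903 calls against 63 in the highest other, and 3172 against 2. In BALB only the real split of all 35 reached 3079, and the highest other, 2410, was the split that follows the code runs. The real split parts every pair of BALB mice, and the 8 splits that do so are too few for a share under 0.05, with 0 in the highest other. For the averaged effect and the interaction 100 regroupings that part every BALB and NOD pair were run, and 100 that ignore the pairs. For the interaction chance cannot be excluded: 7 of the 100 that part the pairs reached 196, the real one included. The other 6, with up to 2938 calls, all set the 3 B6 arrays named above against the rest, which points to that structure, and the highest of the remaining 93 was 16 (3 where deviations were exchanged without regard to pair or strain). For the averaged effect only the real grouping reached its count (1 of 100, 9277 against 3820, and against 2933 where the pairs were ignored), which argues against chance. Only the real split did so for BALB against B6 (1 of 35, 2747 against 541) and NOD against BALB (1 of 35, 2764 against 750). These splits ignore the code runs. No run holds WT mice of both B6 and BALB, and NOD and BALB share a single run, so the splits cannot tell strain from run.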

How the results depend on the processing

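The alternatives chosen after the result was seen are the Gapdh 3'/5' covariate, the covariate of dendritic cell and macrophage markers, merging B6 KO mice 2 and 3, leaving out B6 WT mouse 2 with KO mice 2 and 3, and the code run as a block for the lists. Of 5871 values of named genes under alternatives, 5734 kept their side of the threshold, 116 lost it, 20 gained it and 1 reversed: Kdm5d log2 difference, Aire KO minus WT averaged over strains, read 0.035 without B6 WT mouse 2 and KO mice 2 and 3. Of 219 values of the main results, 165 stayed within 1.5 times the count or 1 SD of the spread ratio. The causes of the changes below were not tested, except where fewer arrays or a fold limit make them plain. With quantile normalization or equal medians no main count moved by over 1.5 times.

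Array weights gave 12733 calls in B6, 6795 in NOD, 16715 averaged, 1702 for the interaction, 6244 for NOD against B6 and 4745 for NOD against BALB. Higher in KO mice were 7181 of these calls in B6, 3390 in NOD and 10129 averaged (1385, 639 and 4740 without weights), so the share of rises grew. The largest weights were 7.66 for B6 KO mouse 3 and 4.40 for NOD WT mouse 2. All others were 1.93 or less, so the weighted fit leans on single arrays. The replicate block gave 9695 in B6, where the numbers do not pair the mice (over the strains 9 of 10 WT arrays correlated best with their own number, the exception being B6 WT mouse 3), 7787 in BALB, 5112 in NOD, 16664 averaged and 1284 for the interaction, and moved no other main count by over 1.5 times; among named genes Eif2s3y, Uty and Nnt gained a call and no other call changed. Higher in KO mice with this block were 4717 in B6, 3891 in BALB, 2200 in NOD and 9461 averaged. The code run as a fixed block gave 4911 in BALB, 3090 in NOD and 381 for the interaction, and as a random block 1179 for BALB against B6 and 1717 for NOD against B6. Fitting only the arrays compared gave 2517 in B6, 938 for BALB against B6, 1355 for NOD against B6 and 1613 for NOD against BALB. Requiring 2-fold besides the test left 1752 in B6, 993 in BALB, 954 in NOD and 1163 averaged, and 2-fold with no test 1954, 1068, 1120 and 1167.

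The Gapdh 3'/5' covariate gave 4519 for BALB against B6 and 6271 for NOD against B6. B6 KO mice 2 and 3 as 1 sample gave 2524 in B6 and 108 for the interaction. Without B6 WT mouse 2 and KO mice 2 and 3, which leaves 1 B6 KO mouse assumed to vary like the other groups, the counts were 1245 in B6, 93 for the interaction, 1713 for BALB against B6 and 2106 for NOD against B6.

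Leaving out 1 mouse at a time gave 2387 to 5307 calls in B6, 2288 to 3413 in BALB, 1180 to 2034 in NOD, 7603 to 9748 averaged, 109 to 223 for the interaction (117 without B6 KO mouse 2, 109 without B6 KO mouse 3, 117 without NOD WT mouse 2, and 114 and 125 without NOD KO mice 2 and 3), 1673 to 2780 for BALB against B6, 1973 to 3389 for NOD against B6 and 1792 to 2700 for NOD against BALB (1792 and 1799 without NOD WT mice 2 and 3). The spread ratio ran from 1.54 to 1.82, and the lists past the threshold from 12 to 13. With camera at an estimated correlation 6 lists passed, and the keratinocyte, mammary, male accessory gland, lung, interferon and cell cycle lists were lost. With fry 23 passed, 21 of them lower: the retina, brain, striated muscle, testis, kidney, endocrine, chemokine, immature medullary epithelium and Aire-independent antigen lists were gained as lower, and mature medullary epithelium and B cells as higher. With the mean of all probe sets of a gene 19 passed, 17 of them lower: the chemokine, striated muscle, testis, kidney and endocrine lists were gained as lower, and antigen presentation and mature medullary epithelium as higher. No signal over background was given, so the level below which differences cannot be seen is unknown.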

Other observations

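No test in this part was chosen after its result was seen. The genes that fell in KO mice included runs of chromosomal neighbours. On chromosome 3, S100a8, S100a9, S100a7l2, Lor and Prr9 of the epidermal differentiation complex were all lower at least 2-fold in the averaged effect, as were Lce1c, Lce1d and Lce1f and the fibrinogen genes Fgg, Fga and Fgb. On chromosome 5 the chemokine genes Cxcl5, Ppbp, Pf4, Cxcl3 and Cxcl15 formed a run of 5, on chromosome 15 the keratins Krt1, Krt77, Krt76 and Krt4 a run of 4, and on chromosome 7 the kallikreins Klk7, Klk6, Klk5 and Klk4 and the serum amyloids Saa3, Saa4, Saa1 and Saa2 runs of 4. Other runs joined genes of different families, such as Gzmc, Gzmb and Atp12a on chromosome 14 and Spx, Gys2 and Ldhb on chromosome 6. These genes were named after their values were seen.

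The test of whether genes that fell sit side by side more often than chance was written before its result was seen. Among 18142 measured genes in RefSeq order, 647 fell at least 2-fold, and they formed 100 pairs of direct neighbours, where 10000 random sets matched on WT level gave a median of 23 (central 95% from 15 to 33). Similar neighbours can share probe sequence, so pairs whose symbols begin with the same 3 letters were left out: 40 pairs remained, against 22 (13 to 31), and 1 of 10000 random sets had as many. Neighbouring genes falling together would give such an excess. Paralogs of different names remain in the count, such as Cxcl5 and Ppbp, Fgg and Fga, or Alb and Afp. Whether an excess is left without them was not tested, so they may account for it.

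The mean log2 of the dendritic cell and macrophage markers was 8.32 in NOD WT mouse 1 and 8.24 in KO mouse 1 of the same code run, and 9.42 and 10.06 in WT mice 2 and 3 and 9.09 and 9.59 in KO mice 2 and 3 of the other run.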
